A study of Mus musculus with 18 samples.

How the data were processed

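Polyadenylated RNA was sequenced from 18 libraries of immortalised mouse embryonic fibroblasts that lack the 3 small Maf proteins MafF, MafG and MafK. There were 2 cell lines, mock cells and cells expressing T-N1G, a fusion that tethers the transcription factor Nrf1 (gene Nfe2l1) to MafG. Each line received vehicle, 0.3 µM or 1.0 µM of the proteasome inhibitor MG132 for 12 h, with 3 libraries in each of the 6 groups. Per the labels' protocols, total RNA was taken with a column kit, and poly(A) selection and a strand-specific library kit followed. Whether the 3 libraries of a group came from separate cultures is not stated, so p-values measure only the spread between these libraries, which may be technical.

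Per the submitters' processing notes, bcl2fastq 2.16.0.10, TopHat2 2.0.8b and Cuffdiff 2.1.1 were used with the mouse build mm9. The gene annotation and any filter are not given in the sources used here, nor is the strand setting of the counting. Per the file headers, the deposited tables hold an estimated count of fragments per gene and library, not scaled between libraries, and the FPKM of each library after Cuffdiff's own scaling. The authors' further table of 1 FPKM value per gene and group was used for the positions of the genes, and their table of scaled counts per group was not used. In each library, 98.16% to 98.51% of the estimated counts deposited were whole within a tolerance of 1e-06, and all were rounded to whole numbers. Libraries carry a number in Cuffdiff's own order, which was taken as the number in the sample titles, and the files do not state this link. It affects only the block, the names of libraries and what is said of same-numbered libraries. Line and dose were read from Cuffdiff's condition names, N1 as T-N1G (spelled T-NG1 in the genotype labels) and L-MG and H-MG as 0.3 and 1.0 µM, which the files do not state either.

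Totals ran from 18164380 to 21293709 fragments per library over 24318 genes. Genes that Cuffdiff left unprocessed in some libraries and lists at 0 there, such as Hspa8 in 9 libraries, were treated as missing and left out of library sizes and tests. A further 20 genes had a failed FPKM estimate in at least 1 library, Nfe2l1 among them, and their fragment counts were kept. Reads are not collapsed by molecular identifiers, so intervals and floors cover counting error only. Libraries of a group were compared in pairs by a chi-square of their counts over genes, whose ratio to its degrees of freedom was 2.92 or more in every pair, so none was counted as a duplicate. Symbols and positions are those of the deposited tables. The reference annotation supplied is of another build and was not used.

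Changes were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test, with TMM scaling, its default expression filter by group and robust dispersion. All 18 libraries entered 1 fit of 6 group means without covariates, in which 13258 genes were tested. The 9 contrasts were T-N1G against mock at each of 3 treatments, each MG132 dose against vehicle in each line, and the interaction of line and dose at each dose. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p for a gene comes from that edgeR test unless another tool is named. Levels are TMM-scaled CPM, given as mean ± SD with n = 3. Standard errors of log2 fold changes were taken as the size of the fold change over the square root of its F statistic. Because all groups share one estimate of spread, the wider spread at 1.0 µM enters the vehicle comparison too. Likewise, the narrower spread of the other groups enters the comparisons at 1.0 µM.

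Before the data were examined, 22 gene lists, the design, the main alternatives and the rule for naming genes were fixed. The lists cover the 14 core and 19 regulatory proteasome subunits, proteasome assembly factors, the immunoproteasome, ubiquitin and p97 factors, antioxidant response element genes, heat shock, the ATF4-led integrated stress response, the unfolded protein response, autophagy, iron and haem handling, cholesterol synthesis, metal response, p53 targets, cell cycle, extracellular matrix, inflammatory genes, the small Maf, CNC and BACH family with Keap1, and markers of leukocytes, endothelium, epithelium, and muscle or fat. Of 430 entries, 427 were in the tables. Lists can share genes. Fth1, Ftl1, Hmox1, Blvrb and Slc48a1 are on both the antioxidant and the iron list, so results of these lists are not independent. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 22 lists of a comparison, and again with an estimated correlation. At the preset correlation camera treats genes of a list as almost independent, which overstates the evidence for coregulated lists. Members were also adjusted over the list alone, and that count is printed where it differs from the count over all genes.

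Named genes were Nfe2l1, Mafg, Maff and Mafk, the genes of largest change in each direction, and up to 4 members of each list with the smallest p. The largest changes were 8 per direction for T-N1G against mock under vehicle and at 1.0 µM, for 1.0 µM against vehicle in each line and for the interaction at 1.0 µM, and 3 per direction for the other comparisons. They needed a mean of 5 CPM in the higher group and, outside the interactions, no overlap between libraries, and unnamed gene models were left out. Some results that the rule or the filters concern are not reported here. Where every library of a group held 0 fragments, the fold is a lower bound against a floor of 3 fragments over the group. With 1 to 3 fragments the ratio of summed counts is given with an exact binomial 95% interval.

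Alternatives were median-of-ratios scaling, library size only, DESeq2 1.42.0, other filters, fits of only the groups compared, an added 2-fold minimum, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, and leaving out each library. On the log2(FPKM + pseudocount) scale, fold changes of low genes are understated. One alternative, leaving out the 1.0 µM libraries numbered 3 in both lines, was chosen after seeing the data because these hold the lowest shares of the ribosomal precursor Rn45s (0.201% and 0.115%) and of ribosomal protein fragments (4.14% and 3.34%) in their groups. Same-numbered libraries deviated together, with each correlation of deviations over 0.1, for 5 of the 7 pairwise comparisons. The lowest were 0.241 for the lines under vehicle, 0.645 for the lines at 1.0 µM, 0.234 and 0.165 for the 2 doses in mock cells, and 0.489 for 0.3 µM in T-N1G cells. This pairing comes from the data and the titles, since no label says what the number marks.

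The edgeR step was tested on simulated counts with 200 genes changed, drawn from the 13258. Changed genes that the expression filter dropped from the simulated counts were counted as not recovered. All groups were given the mean levels of mock cells under vehicle, 1 pooled dispersion per gene and the real library sizes. The wider spread at 1.0 µM and the far larger share of genes called in the data were not simulated, so recovery there may differ. For T-N1G against mock under vehicle, where 12474 genes passed the filter, it recovered 12% of all genes changed 1.25-fold, 76% at 2-fold and 90% at 4-fold. Of its 137 calls 10 were false. For the interaction at 1.0 µM, where 12451 genes passed the filter, it recovered 0%, 64% and 80%, and 6 of 90 calls were false.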

Results

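Transcript levels were measured in 18 libraries of immortalised mouse embryonic fibroblasts without MafF, MafG and MafK, the small Maf proteins with which Nrf1 and related CNC transcription factors bind DNA as heterodimers. Mock cells were compared with cells carrying T-N1G, a tethered Nrf1-MafG heterodimer, after 12 h with vehicle, 0.3 µM or 1.0 µM MG132, an inhibitor of the proteasome. Each of the 6 groups had 3 libraries. Depth was 18751508 to 20739894 fragments per library in mock cells at 1.0 µM, 18164380 to 19095522 in T-N1G cells at 1.0 µM and 19978399 to 21293709 in the other groups. Libraries at 1.0 µM spread further apart than the others. The median SD of log2 CPM over the better expressed genes was 0.1431 in mock and 0.1771 in T-N1G cells at 1.0 µM, against 0.0485 and 0.0628 under vehicle. At 1.0 µM the 10 most abundant genes of a library held 6.83 ± 0.16% of fragments in mock and 7.07 ± 0.30% in T-N1G cells (4.64 ± 0.11% and 4.45 ± 0.12% under vehicle), and ribosomal protein genes held 4.49 ± 0.38% and 3.85 ± 0.46% (5.01 ± 0.17% and 4.67 ± 0.19% under vehicle).

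The targeted genes and the transgene parts were examined first. Mafg (mm9 chromosome 11, 120489667 to 120494861) was nearly absent from mock cells, with 6 to 25 fragments per library, and stood at 158.8 ± 15.6 CPM in T-N1G cells under vehicle. In T-N1G cells it rose to 814 ± 105 CPM at 0.3 µM and 3290 ± 829 CPM at 1.0 µM MG132, a log2 change of 4.37 (SE 0.155, adjusted p = 9.82e-14) at the higher dose. Nfe2l1 (chromosome 11, 96678728 to 96691282), which mock cells also express, was 3.94-fold higher in T-N1G cells under vehicle and rose from 1102 ± 74 to 4637 ± 543 and 17010 ± 3890 CPM with dose. In mock cells Nfe2l1 stood at 279.9 ± 7.0, 375.6 ± 16.8 and 314.9 ± 18.6 CPM. Fragments of Maff and Mafk were present in both lines, and gene totals cannot show whether they come from outside the deleted parts. Maff rose with 1.0 µM MG132 in mock (11.3-fold) and T-N1G cells (12.2-fold), and did not pass the test between the lines at that dose (log2 -0.13, SE 0.173, adjusted p = 0.524).

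**Figure D1:**
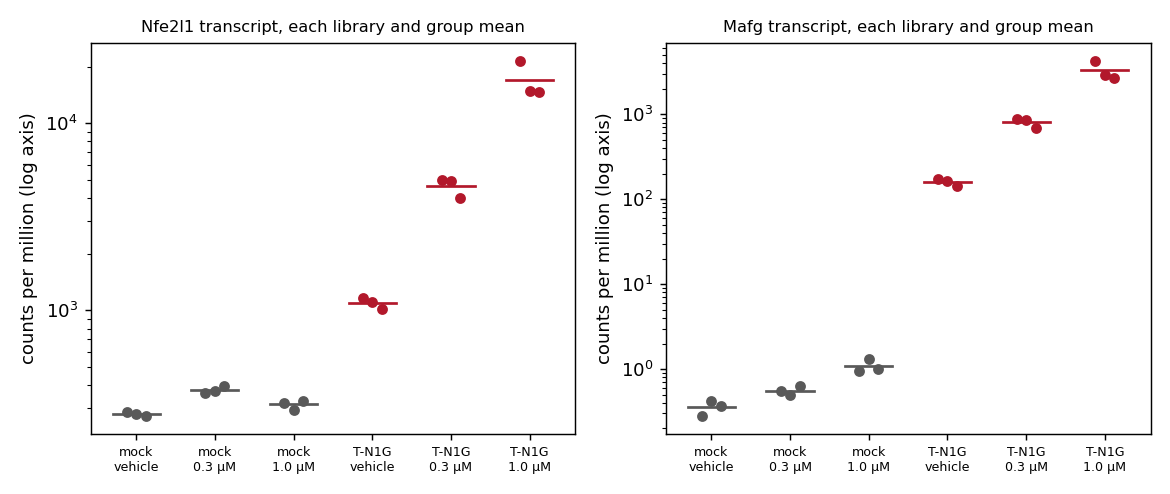
Transcript levels of Nfe2l1 and Mafg in CPM (log axis) in each of the 18 libraries (points) with the mean of each group (bars), mock in grey and T-N1G in red. In T-N1G cells the means of Mafg rose from 158.8 to 3290 CPM with dose, while mock cells stayed near 1 CPM or below.

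The first comparison asked how T-N1G cells differed from mock cells without inhibitor. Antioxidant response element genes, a class bound by CNC-small Maf heterodimers, were higher in T-N1G cells: 14 of 31 passed the test upward and 0 downward (17 and 0 adjusted over the list alone). Among them were Gstm1, a glutathione transferase (7.35-fold, from 3.62 ± 0.26 to 26.6 ± 0.9 CPM), Me1, malic enzyme (3.73-fold), Nqo1, a quinone reductase (3.09-fold), and Gclm, a subunit of the enzyme that starts glutathione synthesis (2.05-fold). The list passed camera (adjusted p = 3.93e-10, and adjusted p = 0.00979 with an estimated correlation). Of the 14 core proteasome subunits 4 were higher (5 adjusted over the list alone) and of the 19 regulatory subunits 5 were higher (6 adjusted over the list alone), 0 of either were lower, and the leading members were Psmd7 (1.7-fold), Psmd1 (1.54-fold), Psma5 (1.45-fold) and Psma1 (1.42-fold). These lists passed camera at the preset correlation (adjusted p = 0.00288 and 0.00198) but not otherwise (adjusted p = 0.628 for both with an estimated correlation). The count of 9 became 21 with 2 lower when only the vehicle groups were fitted, 15 without T-N1G replicate 1 at 1.0 µM and 16 without the number 3 libraries of 1.0 µM, which were left out after seeing the data.

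Iron genes, matrix genes and the Maf family also held members that were higher under vehicle. In iron and haem handling 5 of 17 were higher and 0 lower (6 and 0 adjusted over the list alone), with Slc40a1, the iron exporter, 4.44-fold higher and Fth1, ferritin heavy chain, 1.86-fold higher (camera adjusted p = 0.0265, and adjusted p = 0.35 with an estimated correlation). In the extracellular matrix list 6 of 29 were higher and 0 lower, including Myl9 (3.66-fold) and Col5a2 (1.6-fold) (adjusted p = 0.000861, and 0.35 with an estimated correlation). Of 9 genes of the small Maf, CNC and BACH family and its regulator Keap1, 5 were higher and 0 lower (adjusted p = 0.000258, and 0.0769 with an estimated correlation). Among the 5 are Nfe2l2 (1.57-fold), Keap1 (1.34-fold) and the introduced Mafg and Nfe2l1, so the test includes the transgene. Of 30 integrated stress response genes 8 were lower and 1 was higher (9 and 2 adjusted over the list alone), among them Asns, asparagine synthetase (log2 -0.58) (adjusted p = 0.00136, and 0.35 with an estimated correlation). Of 20 p53 targets 5 were lower and 1 was higher (8 and 1 adjusted over the list alone), with Ccng1 at log2 -0.62 (adjusted p = 0.00288, and 0.35 with an estimated correlation). Of 22 unfolded protein response genes 3 were higher and 0 lower (adjusted p = 0.0297, and adjusted p = 0.628 with an estimated correlation).

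Across all genes 2141 of 13258 passed the test under vehicle, 1118 higher and 1023 lower in T-N1G cells, and 508 of them by 2-fold or more. Besides Mafg and Gstm1, the largest increases were in Spock3 (68.2-fold), Mgst1, a microsomal glutathione transferase (31.1-fold), Ttn (14.7-fold), Scara5 (13.4-fold), Igfbp5 (12.5-fold) and Mest (8.03-fold). The largest decreases included Zdbf2 (chromosome 1, 63229145 to 63361149), which had 511 fragments over the mock libraries and 0 over the T-N1G libraries and was at least 170-fold lower. Upk1b (log2 -5.68), Adcyap1r1 (-4.77), Gpm6a (-3.89), Ms4a2 (-3.61), Hook1 (-2.77), Ppl (-2.75) and Cck (-2.57) followed. Genes of chromosomes 4 and 11, 14.7% of those tested, made up 44.8% of the lower calls (458 of 1023) and 7.7% of the higher calls (86 of 1118). The count depends on the libraries that share the fit. With only the 2 vehicle groups 4882 genes passed, and leaving out mock replicate 1, mock replicate 2 or T-N1G replicate 1 under vehicle gave 1407, 1311 and 1301.

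The second question was what MG132 did without small Maf proteins. In mock cells the proteasome genes did not move together. At 1.0 µM, 3 of 14 core subunits rose and 7 fell, and 9 of 19 regulatory subunits rose and 4 fell, and the list tests did not pass (camera adjusted p = 0.256 and 0.174). The median log2 change over the 33 genes was 0.02, and it was -0.07 when scaled by library size only, so its sign depends on the scaling. Psma5, a core subunit (chromosome 3, 108059844 to 108082870), fell from 67.4 ± 3.3 to 34.4 ± 1.5 CPM (log2 -0.97, SE 0.098, adjusted p = 9.17e-08), and Psma2 fell as well (log2 -0.88). Adrm1, a ubiquitin receptor of the proteasome, rose 1.76-fold and Psmc2 rose 1.7-fold. At 0.3 µM, 2 core subunits rose and 4 fell, and 7 regulatory subunits rose and 1 fell (regulatory list adjusted p = 0.0265, and adjusted p = 0.759 with an estimated correlation). With only the 2 groups compared, 19 of the 33 rose and 8 fell at 0.3 µM. Of 31 antioxidant response element genes 10 rose and 19 fell at 1.0 µM (camera adjusted p = 0.162), with Hmox1, haem oxygenase, up 5.88-fold and G6pdx (log2 -1.49), Pgd (-1.09) and Gstp1 (-1.52) down.

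Stress genes rose in mock cells at both doses. Of 24 heat shock genes 23 rose at 0.3 µM and 23 at 1.0 µM, where 1 fell, with medians of 1.249 and 1.92 on the log2 scale (camera adjusted p = 1.18e-16 and 7.42e-15; adjusted p = 0.0609 and 0.0889 with an estimated correlation). Hspa1b, an inducible Hsp70 (chromosome 17, 35093374 to 35096183), went from 23.4 ± 1.3 to 3721 ± 912 CPM (159-fold), and Hsph1 rose 18.9-fold. Hspa1a and Hspa1b are near-identical copies, so how their reads were divided is uncertain. Of 30 integrated stress response genes 24 rose at each dose, with 0 and 1 falling (25 and 1 adjusted over the list alone at 0.3 µM), led by the transcription factors Atf3 (64.8-fold at 1.0 µM) and Ddit3 (3.67-fold) and by Ppp1r15a (11.7-fold) (adjusted p = 1.65e-10 and 2.55e-08; 0.0609 and 0.0889 with an estimated correlation). Autophagy and lysosome genes rose too, 17 of 27 at 1.0 µM with 4 falling, and the cargo receptor Sqstm1 rose 4.2-fold (adjusted p = 0.00152, and 0.188 with an estimated correlation). In the ubiquitin and p97 list 14 of 19 rose and 4 fell, with Zfand2a up 17-fold and Ubb, a polyubiquitin gene, up 6.22-fold (adjusted p = 0.00515, and 0.419 with an estimated correlation).

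Of 24 cholesterol genes 19 fell and 1 rose at 1.0 µM in mock cells, among them Acat2 (log2 -2.07), Mvd (-1.76) and Mvk (-1.69) (adjusted p = 0.000142, and 0.51 with an estimated correlation). Of 35 cell cycle genes 22 fell and 9 rose, including Ccnb1 (-1.67), Plk1 (-1.66) and Aurkb (-1.77) (adjusted p = 0.0415, and 0.811 with an estimated correlation). The transferrin receptor Tfrc fell by 2.12 on the log2 scale, one of 10 of 17 iron and haem genes that fell while 3 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.162). Inflammatory genes rose in part, 13 of 24 with 4 falling (15 and 4 adjusted over the list alone), led by Il6 (92.8-fold), Ptgs2 (14.5-fold) and Tnfaip3 (6.06-fold) (adjusted p = 0.00665, and 0.579 with an estimated correlation). The unfolded protein response list went both ways, with 6 rising and 10 falling of 22 (adjusted p = 0.546), as did the 20 p53 targets with 8 and 7 (adjusted p = 0.424), of which Gadd45a rose 9.99-fold. Matrix genes fell in 12 of 29 cases and rose in 6 (adjusted p = 0.49), with Sparc at log2 -1.85. Of the 5 metal response genes 1 rose and 3 fell (adjusted p = 0.753).

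In all, 7040 genes passed at 0.3 µM (3310 higher, 3730 lower) and 9244 at 1.0 µM (4292 higher, 4952 lower) in mock cells, 1424 and 3364 by 2-fold or more. At 1.0 µM the largest increases were in genes at or near 0 under vehicle. Krtap4-16 and Mmp10 had 0 fragments there and were at least 349-fold and 276-fold higher. Nts (ratio 463, 95% interval 82.6 to 18300), Cpn1 (421, 75 to 16700) and the collagenase Mmp13 (266, 90.8 to 1300) had 1 to 3 fragments under vehicle. Hspa1a rose 290-fold, Serpinb2 188-fold and Dynap 173-fold. The largest decreases were in Aldh1a1 (log2 -4.72), S100a4 (-3.92), Tmem119 (-3.54), Cd248 (-3.12), Ms4a2 (-3.11), Atoh8 (-3.09) and Map2k6 (-3.01). Oaz1-ps (-4.36) is named by the rule, but as a pseudogene it shares reads with its parent gene and its mean at 1.0 µM was 11.4 ± 19.7 CPM, so its value is uncertain. At 0.3 µM the leading genes were Hspa1a (35.4-fold), Hspa1b (26.7-fold) and Atf3 (21.7-fold), and Ms4a2 (-3.15), Gas1 (-3.15) and Adamts5 (-3.04) fell most.

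The third question was how T-N1G cells answered the same doses. Here the proteasome genes rose together. All 14 core subunits rose at both doses, as did 18 of 19 regulatory subunits, and 0 fell (1 fell adjusted over the list alone at 1.0 µM). Medians over the 33 genes were 1.29 at 0.3 µM and 1.47 at 1.0 µM on the log2 scale, and 1.23 and 1.32 when scaled by library size only. The lists passed camera at 0.3 µM (adjusted p = 7.91e-09 and 3.45e-11) and 1.0 µM (1.39e-05 and 2.22e-08). With an estimated correlation they did not, with adjusted p = 0.206 for both lists at 0.3 µM and adjusted p = 0.364 and 0.299 at 1.0 µM. Psma5 went from 98 ± 8.3 to 262.0 ± 16.6 and 284.5 ± 45.3 CPM, and Psmd11, a lid subunit (chromosome 11, 80242117 to 80285635), from 154.3 ± 4.6 to 576.9 ± 24.1 and 729.0 ± 68.3 CPM. The exception in T-N1G cells was Shfm1, a regulatory subunit picked out after its values were seen, at log2 -0.32 and -0.42. Factors near the proteasome moved as well: Usp14, a deubiquitinase of the 19S particle, rose 3.05-fold and Psme4, an alternative activator, 2.93-fold at 1.0 µM, where 8 of 15 associated factors rose and 5 fell (adjusted p = 0.0905).

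**Figure D2:**
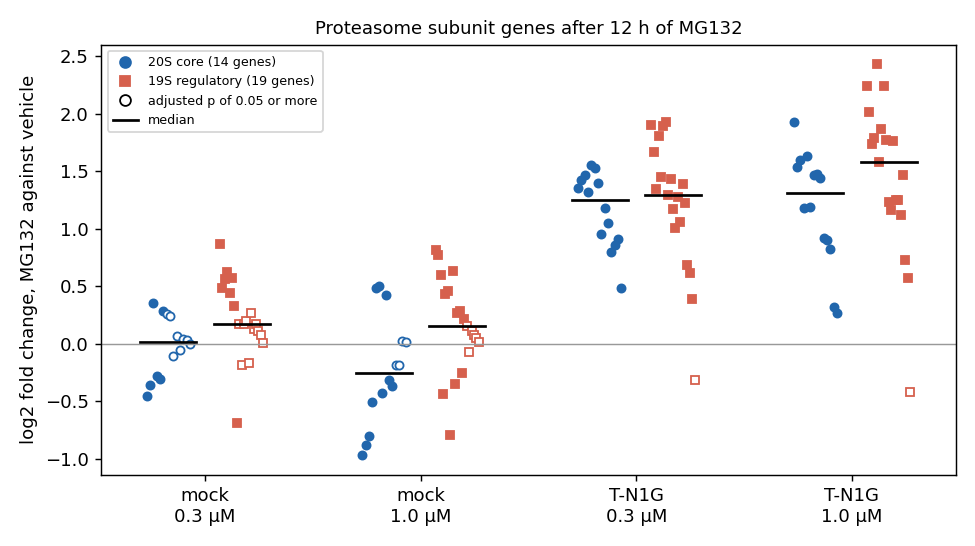
Log2 fold change of each of the 33 proteasome subunit genes after 12 h of MG132 against vehicle, in mock and T-N1G cells at 0.3 and 1.0 µM, with circles for core and squares for regulatory subunits, open symbols where the test was not passed and bars for the median of each class. Mock values lie on both sides of 0, where the median of all 33 at 1.0 µM is 0.02 and turns to -0.07 when scaled by library size only, and T-N1G values lie above 0 except Shfm1.

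Antioxidant response element genes rose in T-N1G cells, 26 of 31 at 0.3 µM with 1 falling (camera adjusted p = 2.33e-08, and 0.0281 with an estimated correlation) and 22 at 1.0 µM with 5 falling (0.000627, and 0.22 with an estimated correlation). Srxn1, sulfiredoxin, rose 12.4-fold and Blvrb, biliverdin reductase B, 6.3-fold at 1.0 µM. Stress lists rose here too. Of 24 heat shock genes 22 rose at 0.3 µM and 23 at 1.0 µM (adjusted p = 3.45e-11 and 2.84e-10; 0.0994 and 0.22 with an estimated correlation), with Hspa1b up 214-fold. Integrated stress response genes rose in 22 and 20 of 30 cases and fell in 2 and 6 (3 fell at 0.3 µM adjusted over the list alone; adjusted p = 5.25e-07 and 0.000466; 0.0994 and 0.279 with an estimated correlation), and Sqstm1 rose 9.56-fold and 12.9-fold. Cholesterol genes fell in 19 and 20 of 24 cases and rose in 0 and 1 (2 rose at 1.0 µM adjusted over the list alone), with Dhcr7 at -2.34 (adjusted p = 2.15e-05 and 0.000152; 0.397 and 0.489 with an estimated correlation). Cell cycle genes fell in 22 and 23 of 35 and rose in 3 and 4 (4 rose at 0.3 µM adjusted over the list alone), with Ube2c at -2.97 (adjusted p = 0.000989 and 0.000235; 0.621 and 0.492 with an estimated correlation). Matrix genes fell in 18 and 14 of 29 cases and rose in 2 and 6 (adjusted p = 0.000784 and 0.121; 0.206 and 0.584 with an estimated correlation), with Col3a1 at -2.02 and Loxl1 at -1.79 at 0.3 µM.

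In T-N1G cells 7872 genes passed at 0.3 µM (3858 higher, 4014 lower) and 10124 at 1.0 µM (4973 higher, 5151 lower), 2162 and 4804 by 2-fold or more. The largest increases at 1.0 µM were in Hspa1a (461-fold), Sstr5 (ratio 605, 95% interval 108 to 23900), Mmp13 (389, 69.3 to 15400), Hspa1b, Igsf11 (232, 78.9 to 1130), Srpx2 (224, 76.2 to 1090), Serpinb2 (146-fold) and Prdm1 (173, 47.4 to 1430). The largest decreases, leaving aside Oaz1-ps (-4.66), were in S100a4 (-4.41), Cd248 (-4.30), Adamts5 (-4.23), Sdpr (-3.99), Sfrp1 (-3.93), Atoh8 (-3.87) and Ptprv (-3.85). At 0.3 µM Rnf183 (38.0-fold), Afp (25.5-fold) and Atf3 (16.5-fold) rose most and Adamts5 (-3.57), Wscd2 (-3.53) and Prelp (-3.41) fell most. The MG132 responses of the 2 lines, which share no library, overlapped. At 1.0 µM 3158 genes rose in both (1609.9 for independent lists) and 3691 fell in both (1924), while 286 rose in mock and fell in T-N1G cells and 494 did the reverse. Log2 changes correlated across genes at 0.758, where genes are not independent replicates.

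The difference between the 2 responses was tested as an interaction. For 31 of the 33 proteasome subunit genes the rise with MG132 was larger in T-N1G than in mock cells at each dose, and 0 went the other way, with all 14 core and 17 of 19 regulatory subunits. Median interactions were 1.17 at 0.3 µM and 1.38 at 1.0 µM on the log2 scale. Psma5 had the largest, 1.78 (SE 0.134) and 2.51 (SE 0.136, adjusted p = 2.56e-10), followed among the leading members at 1.0 µM by Psmd11 (2.03), Psmb4 (1.90), Psma1 (1.78) and Psmc5 (1.70). At 1.0 µM camera gave adjusted p = 9.73e-11 for the core and 5.74e-13 for the regulatory list, and adjusted p = 0.205 for both with an estimated correlation. Antioxidant response element genes differed in the same direction, 25 of 31 at 0.3 µM and 23 at 1.0 µM with 1 the other way at each dose (27 and 1 at 0.3 µM adjusted over the list alone, camera adjusted p = 1.13e-16 and 4.92e-10; 0.00117 and 0.0124 with an estimated correlation), led by Blvrb, Pgd and Srxn1 (7.67-fold, 3.17-fold and 7.53-fold at 1.0 µM). Hmox1 went the other way, with an interaction of -1.15 at 1.0 µM (SE 0.239, adjusted p = 0.000789), and its level at that dose was 6643 ± 1444 CPM in mock and 2433 ± 781 CPM in T-N1G cells.

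Other lists differed between the lines in either direction. The interaction at 0.3 µM was above 0 for 10 of 27 autophagy genes and below 0 for 1 (11 and 1 adjusted over the list alone, adjusted p = 0.0132, and 0.244 with an estimated correlation). At 1.0 µM it was above 0 for 12 and below 0 for 4 (12 and 5 adjusted over the list alone, adjusted p = 0.261), and Sqstm1 had an interaction of 1.62. For iron and haem genes it was above 0 in 10 of 17 cases at 1.0 µM and below 0 in 4 (11 and 4 adjusted over the list alone, adjusted p = 0.00673, and 0.205 with an estimated correlation), including the haem transporters Abcb6 (5.56-fold) and Slc48a1 (4.03-fold). Slc48a1 is on the antioxidant response element list too. The ubiquitin and p97 factors Nploc4 (3.05-fold), Ufd1l (2.64-fold) and Zfand5 (2.81-fold) were among 11 of 19 above 0 at 1.0 µM, with 2 below (12 and 2 adjusted over the list alone, adjusted p = 0.000686, and 0.229 with an estimated correlation). For cell cycle genes it was below 0 in 19 of 35 cases at 1.0 µM and above 0 in 1 (20 and 2 adjusted over the list alone, adjusted p = 0.000689, and 0.707 with an estimated correlation). Heat shock genes did not differ as a list at 1.0 µM (3 above and 7 below 0 of 24, adjusted p = 0.687). At 0.3 µM 6 were below and 2 above 0 (8 and 2 adjusted over the list alone, adjusted p = 0.0252, and 0.612 with an estimated correlation), with Hsph1 at -0.94. Further lists lay below 0 at 0.3 µM at the preset correlation and did not pass at 1.0 µM. They were inflammatory genes, with 5 of 24 below and 0 above 0 at 0.3 µM (adjusted p = 0.00808, then 0.687 at 1.0 µM), matrix genes with 4 of 29 and 0 (2 and 0 adjusted over the list alone, 0.00926, then 0.157) and cholesterol genes with 3 of 24 and 1 (2 and 1 adjusted over the list alone, 0.0108, then 0.351). With an estimated correlation they had adjusted p = 0.612, 0.424 and 0.701 at 0.3 µM. For proteasome assembly and associated factors the interaction was above 0 in 8 and 9 of 15 cases at the 2 doses and below 0 in none (9 and 0 at 0.3 µM adjusted over the list alone, adjusted p = 5.09e-06 and 0.000686; 0.0822 and 0.205 with an estimated correlation). The unfolded protein response (4 above and 5 below 0 of 22, adjusted p = 0.843) and the immunoproteasome (1 and 1 of 7, 0 and 1 adjusted over the list alone, adjusted p = 0.863) did not pass at 1.0 µM.

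Over all genes 3332 interactions passed at 0.3 µM (1878 above and 1454 below 0) and 5964 at 1.0 µM (3038 and 2926). At 1.0 µM the largest above 0 were in Fam13a (log2 5.31, from 4.68 ± 0.60 to 89.97 ± 10.12 CPM in T-N1G cells), Cd1d1 (4.196), Cd40 (4.18), Ttll11 (3.88), Nfe2l1 (3.78), Fbxo2 (3.75) and Map1a (3.75). Srpx2 ranked first by the fit (9.41, SE 3.039), which is no bound because mock cells held 0 fragments at 1.0 µM. The largest below 0 were in Trp63 (-3.39), Inhbb (-3.00), Cldn1 (-2.99), Map3k7cl (-2.93), Krt8 (-2.92), Plekha6 (-2.84), Sprr1a (-2.82) and Fibin (-2.78). At 0.3 µM they were Fam13a (4.195), Fbxo2 (3.74) and Snx29 (3.16) above, and Plekha6 (-3.08), Gjb2 (-2.34) and Dhrs3 (-2.34) below 0. With only the 4 groups compared, 5873 interactions passed at 0.3 µM and 5099 at 1.0 µM.

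The lines were also compared directly under MG132. All 14 core and 17 of 19 regulatory subunits were higher in T-N1G cells at both doses, with medians over the 33 genes of 1.299 and 1.55 on the log2 scale. Psma5 was 4.98-fold and 8.26-fold higher and Psmd11 3.77-fold and 5.16-fold. Camera gave adjusted p = 3.91e-10 and 7.95e-12 for the 2 lists at 1.0 µM, and adjusted p = 0.242 for both with an estimated correlation. Antioxidant response element genes were higher in 27 and 26 of 31 cases with 1 lower at each dose (29 and 1 at 0.3 µM adjusted over the list alone, adjusted p = 3.4e-17 and 7.95e-12; 0.000926 and 0.00515 with an estimated correlation). At 1.0 µM Blvrb was 13.9-fold, Nqo1 12.1-fold, Slc48a1 10.8-fold and Gclm 5.99-fold higher. Iron and haem genes were higher in 13 and 11 of 17 cases and lower in 2 and 3 (adjusted p = 0.000172 and 0.0029; 0.0715 and 0.22 with an estimated correlation). Integrated stress response genes were lower in 12 and 19 of 30 cases and higher in 3 and 4, with Stc2 at -2.58 and Pycr1 at -1.56 at 1.0 µM (adjusted p = 0.0266 and 0.00517; 0.502 and 0.368 with an estimated correlation).

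The lines differed in 6433 genes at 0.3 µM (3315 higher, 3118 lower in T-N1G cells) and 8209 at 1.0 µM (4065 higher, 4144 lower), 1515 and 2571 by 2-fold or more. With only the 2 groups compared, 7914 genes passed at 0.3 µM and 5715 at 1.0 µM. Besides Mafg, the largest increases at 1.0 µM were in Srpx2 and Sstr5, with 0 fragments in mock cells (at least 198-fold and 178-fold), Nlrp4e (ratio 564, 95% interval 156 to 4660), Rnf183 (120-fold), the ferroxidase Heph (115-fold), the efflux pump Abcc2 (73.0-fold) and Fam13a (56.9-fold). The largest decreases included Zdbf2 (-8.23), Adcyap1r1 (ratio 139, 95% interval 38.1 to 1150), Cldn1 (-5.32), Dkk2 (-4.85), Ripk4 (-4.28), Hook1 (-3.95) and Sorbs2 (-3.76). At 0.3 µM Nlrp4e (0 fragments in mock cells, at least 168-fold) and Mgst1 (174-fold) were the largest increases after Mafg, and Zdbf2 (-6.86), Ctsc (-4.43) and Ripk4 (-3.91) the largest decreases. Between the comparisons under vehicle and at 1.0 µM, which share no library, 532 genes were higher in both (342.8 for independent lists) and 669 lower in both (319.8), while 219 went from higher to lower and 132 from lower to higher.

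Markers of other cell types were followed alongside. In mock cells 5 of 6 epithelial markers rose at 1.0 µM and 0 fell (adjusted p = 0.00887, and 0.0889 with an estimated correlation), with Krt8 up 30.3-fold to 8.07 ± 2.65 CPM and Cldn4, at 0 fragments under vehicle, at least 49.1-fold higher. In T-N1G cells 4 of 6 rose at 1.0 µM and 1 fell (adjusted p = 0.354). Compared with mock cells, 4 of 6 were lower in T-N1G cells and 0 were higher at both 0.3 and 1.0 µM (adjusted p = 0.0158 and 0.14; 0.12 and 0.259 with an estimated correlation), with Krt19 at -2.98 at 1.0 µM. The interaction was below 0 for 3 at 0.3 µM and 2 at 1.0 µM and above 0 for none (adjusted p = 0.00789 and 0.0764; 0.0677 and 0.205 with an estimated correlation). Endothelial markers rose in 4 of 7 cases at 1.0 µM in mock and 5 of 7 in T-N1G cells (adjusted p = 0.0571 and 0.0815), among them Kdr (12.9-fold and 7.19-fold). Of 4 leukocyte markers 3 and 4 rose (adjusted p = 0.177 and 0.0815), where Ptprc had 1 to 2 fragments over a vehicle group. Muscle and fat markers went both ways, with 2 of 7 rising and 3 falling in mock cells (2 and 4 adjusted over the list alone, adjusted p = 0.753).

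**Figure D3:**
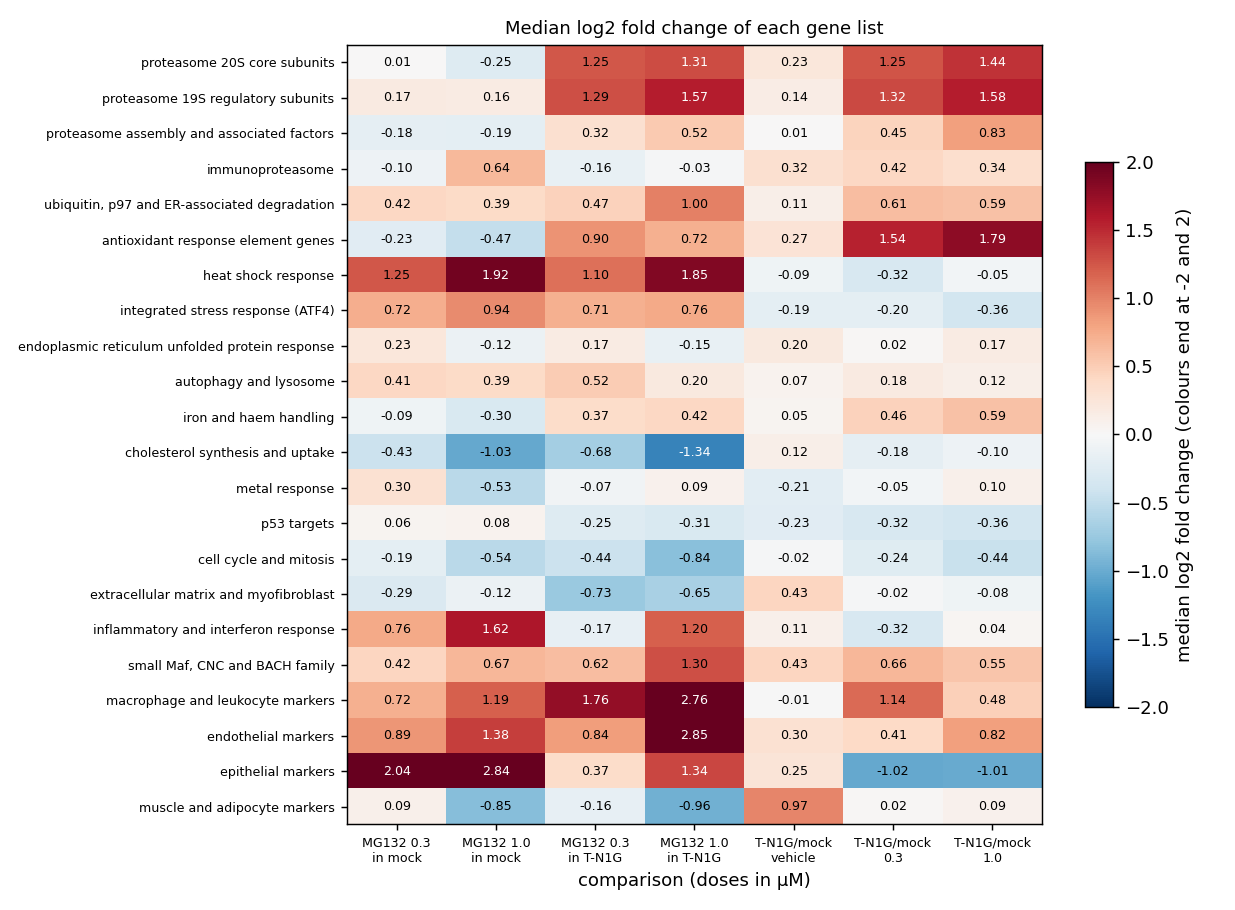
Median log2 fold change of the measured members of each of the 22 gene lists (down) in 7 comparisons (across), red above and blue below 0, with colours ending at -2 and 2 and the value printed in each cell. The core and regulatory proteasome lists and the antioxidant response element list have medians above 0.7 with MG132 in T-N1G cells, and heat shock medians are above 1 with MG132 in both lines.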

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

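The tests of scaling, transcript amount, depth and shared replicate numbers in this part were chosen only after the results were seen, as were the bootstrap interval beside the ratio of line differences, both tests of copy number split by chromosome and the dispersion of the splits.

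The MG132 effect differed between the 2 lines by the interaction test for 3332 genes at 0.3 µM and 5964 at 1.0 µM, 31 proteasome subunit genes at each dose, and antioxidant response element genes with medians of 0.83 and 1.02 on the log2 scale. The single genes with the largest such differences at 0.3 µM were Fam13a (4.195), Fbxo2 (3.74), Snx29 (3.16), Plekha6 (-3.08), Gjb2 (-2.34) and Dhrs3 (-2.34). At 1.0 µM they were Srpx2 (9.41), Fam13a (5.31), Cd1d1 (4.196), Cd40 (4.18), Ttll11 (3.88), Nfe2l1 (3.78), Fbxo2 (3.75), Map1a (3.75), Trp63 (-3.39), Inhbb (-3.00), Cldn1 (-2.99), Map3k7cl (-2.93), Krt8 (-2.92), Plekha6 (-2.84), Sprr1a (-2.82) and Fibin (-2.78). In data that no test used, Hspa8, left unprocessed by Cuffdiff in 9 libraries, held 2.85 times the share of fragments in T-N1G cells at 0.3 µM (1.23 ± 0.05%) as under vehicle (0.431 ± 0.019%). Groups of 3 are too small for a test of outlying libraries.

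Other splits of the libraries were counted for every contrast. For the 7 pairwise contrasts 3 against 3 gives 10 splits, too few for a share under 0.05, and in each the real split gave the most genes (1 of 10). The real counts were 2141, 6433 and 8209 between the lines by dose, 7040 and 9244 in mock and 7872 and 10124 in T-N1G cells, and the highest other split gave 291 genes for the lines at 1.0 µM and 0 for the rest. For proteasome genes the real counts were 9, 31, 31, 14, 23, 32 and 32, and the highest other split gave 0. The other splits mix 2 groups that differ. By contrast, this raised the common dispersion by a median of 1.55 times (lines under vehicle) to 6.32 times (1.0 µM in T-N1G cells). Their low counts are thus partly built in and leave chance open. For the interaction at 0.3 µM 99 other splits were drawn. Of the 100 with the real one, 2 gave as many genes as the real 3332, namely the real one itself and 1 with 4053. That other split kept the 3 T-N1G libraries at 0.3 µM together and mixed the other 3 groups. At 1.0 µM 1 of 100 gave as many genes as the real one, which was the real one itself with 5964, against 5259 in the highest other. For the 31 proteasome genes it was 1 of 100 at each dose, with 30 and 29 in the highest other split. These splits mix lines and doses that differ, which raised the common dispersion by a median of 5.89 times at 0.3 µM and 11 times at 1.0 µM, so they do not test the interaction by itself and leave chance open.

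The first pattern is the rise of proteasome genes with MG132 in T-N1G cells and not, as a group, in mock cells. The choice among 3 scalings was argued against: the lowest of 3 medians of the interaction at 1.0 µM was 1.32 (library size only), where an effect of scaling would have brought it under 0.1. That bound could hardly be reached. Median-of-ratios scaling and library size only moved interactions by medians of just -0.033 and -0.051 from TMM. All 3 rest on the same counts, so the test cannot decide on scaling in general. The amount of T-N1G transcript stays open, since Mafg and Nfe2l1 transcripts rose with dose in the same cells. From 0.3 to 1.0 µM Mafg rose by 2.02 on the log2 scale and the line difference of the subunits by a median of 0.311, so a response that saturates cannot be told apart from one set by the inhibited proteasome. Activity of T-N1G is the explanation the design names, and it may act through its amount, its protein or both. With 2 cell lines in all, T-N1G cannot be told apart from any other difference between the lines in their response to MG132, such as clonal origin.

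The second pattern is the set of 506 genes, transgene parts aside, that differed 2-fold or more between the lines under vehicle. The difference they were chosen on is also the divisor of the ratios below and enters the interaction. Selection by itself can therefore lower these ratios and add smaller interactions. A fixed difference between the lines, such as clonal origin, stays open for the 312 higher genes: their difference at 1.0 µM was a median 0.486 of that under vehicle (bootstrap 95% interval 0.364 to 0.631), not past the bound of 0.5 by more than its spread, although the interaction test found it smaller for 126 of them and larger for 41. For the 194 lower genes the median ratio was 1.07 (quartiles 0.597 to 1.498), as a fixed difference would give for the set. The interaction test found the difference larger for 43, which a fixed difference would not give, and smaller for 30, to which selection can add. A fixed difference is thus only a candidate explanation for the set. A clonal difference that changes with MG132 was not tested. Off chromosomes 4 and 11, 0 of 215 windows of 50 neighbouring genes shifted by over 0.25 in all 3 treatments. This argues only against broad copy number changes of that size there. Smaller shifts can go unseen, since on chromosomes 4 and 11 only 4 of 38 windows went past this bound. Changes narrower than a window were not searched. Chromosomes 4 and 11 hold all 4 shifted windows of 253 and 68 of the 506 genes, 36 lower and 32 higher. Their lowest window median under vehicle was -0.283. A shift of whole windows by that much is too small to be the whole cause of a 2-fold difference. Of the difference of the 36 lower genes a median share of 0.901 (bootstrap 95% interval 0.863 to 0.923) was left without their window's median. That share follows from these sizes and the choice of genes, so it is no separate evidence. The higher genes do not decide it either. A window of chromosome 4 with 8 of the 506 genes lay above 0 in all 3 treatments (0.335, 0.113 and 0.454).

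The third pattern is the wider spread of replicates at 1.0 µM. Depth was argued against, since the SD grew at least 2.66 times more than depth allows in both lines. Shared handling of same-numbered libraries is in line with the correlation of their deviations between the lines, 0.645 at the lowest, but no label says what the number marks. Libraries that differ in the strength of the response stay open: for the library farthest from its group the correlation with the other line's response was 0.189 in size in mock cells, under the 0.3 required, and -0.381 in T-N1G cells. No biological explanation was tested.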

How the results depend on the processing

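Counts of called genes kept within 1.5 times of the main value except as given here; DESeq2, both other scalings, both other filters and the 3 limma fits on FPKM moved none beyond that. Adding a 2-fold minimum left 508, 1515 and 2571 genes between the lines by dose, 1424 and 3364 in mock cells, 2162 and 4804 in T-N1G cells, and 842 and 2006 interactions, by its own construction. Under it 0 proteasome genes remained for T-N1G against mock under vehicle and for either dose in mock cells, and 20 for the interaction at 0.3 µM. Fitting only the groups compared gave 4882 genes and 21 proteasome genes for the lines under vehicle. It gave 27 proteasome genes at 0.3 µM in mock cells and 5873 interactions at 0.3 µM. These fits leave out the noisier groups, though the cause was not tested. Within 1.5 times, the same setting lowered the lines at 1.0 µM from 8209 to 5715 genes, which kept 69.59% of the main calls. That fit leaves out the quieter groups. Interactions at 1.0 µM fell from 5964 to 5099, with 85.24% of the main calls kept. Leaving out the 1.0 µM libraries numbered 3 of both lines, chosen after seeing the data, gave 16 proteasome genes under vehicle instead of 9. Leaving out each library gave 1301 to 2609 genes and 8 to 15 proteasome genes under vehicle, the 15 without T-N1G replicate 1 at 1.0 µM. For the other contrasts the range stayed within 1.5 times. Scaling by library size only lowered log2 changes by a median of 0.142 for 1.0 µM in T-N1G cells; no scaling moved the share of higher calls by over 10 percentage points. Which direction held more calls nevertheless depends on the scaling, except for the lines at 1.0 µM and the interaction at 0.3 µM. For 0.3 µM in T-N1G cells no scaling gave more higher calls, though median-of-ratios scaling gave 3933 in each direction. For 1.0 µM in mock cells median-of-ratios scaling gave 4799 higher and 4406 lower, and library size only 3790 and 5448.

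With the replicate block 2608 genes passed under vehicle and 5964 interactions at 1.0 µM became 6388. The block ended 2 of the list tests, inflammatory genes between the lines at 0.3 µM (adjusted p = 0.0593) and iron genes at 0.3 µM in T-N1G cells (0.0528), ended 1 call of a named gene and added 14. It changed no other list test or count by over 1.5 times. The numbers did not pair the lines at 0.3 µM or 1.0 µM against vehicle in T-N1G cells. With an estimated correlation 88 list tests were no longer past the threshold. Over all fits that leave out 1 library, 18 list tests were lost and 19 gained; 4 were lost without the libraries numbered 3, 9 were gained without a low-count filter, 2 were gained with library size only, 1 was lost and 1 gained with median-of-ratios scaling and with the 1 CPM filter, and 2 were lost and 3 gained with only the groups compared. Calls of named genes lost and gained numbered 355 and 65 over the fits that leave out 1 library, 7 and 12 without the libraries numbered 3, 10 and 9 with DESeq2, 12 and 4 with library size only, 4 and 5 with median-of-ratios scaling, 15 and 0 without a low-count filter, 0 and 2 with the 1 CPM filter, 9 and 22 with only the groups compared, 5 and 3 with limma on log2(FPKM + 1), 35 and 2 with that and no filter, and 6 and 4 on log2(FPKM + 0.1). Of the named genes 1 reversed: the interaction of Myh3 at 1.0 µM, a gene of few fragments, was -0.36 and not called in the main test and 0.28 with limma on log2(FPKM + 1) without a filter; the cause was not tested. Depth of 18164380 to 21293709 fragments limits genes with few fragments, whose folds are bounds or carry intervals.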

Other observations

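The gene families of this part and the test of chromosomes were chosen only after the other results were seen.

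Further gene families were counted after MG132. At 1.0 µM in mock cells 10 of 12 keratins and 5 of 6 claudins, some of them also on the list of epithelial markers, rose and 0 fell (median log2 2.95 and 2.49, adjusted p = 0.0703 for both with an estimated correlation). In T-N1G cells at that dose 9 keratins rose and 2 fell (2.42) and 5 claudins rose and 1 fell (3.15, adjusted p = 0.702 for both with an estimated correlation). Some members were at or near 0 under vehicle, such as Cldn4 with 0 fragments in both lines and Krt18 with 3 in T-N1G cells. The fitted changes of such genes are uncertain in size, and so are these medians. In mock cells 7 of 7 chaperonin subunits rose at 1.0 µM (0.55, adjusted p = 0.495 with an estimated correlation), as did 7 in T-N1G cells (0.49, adjusted p = 0.721 likewise). Complex I genes, subunits and assembly factors together, fell in 39 of 44 cases with 0 rising (-0.89, adjusted p = 0.378 with an estimated correlation; 28 fell and 5 rose in T-N1G cells) and mitochondrial ribosomal proteins in 47 of 77 with 17 rising (-0.39, adjusted p = 0.618 likewise). In T-N1G cells 27 of 33 Hox genes fell at 1.0 µM and 0 rose (-1.05, adjusted p = 0.702 with an estimated correlation), and the interaction was below 0 for 16 and above 0 for 0 of them (adjusted p = 0.475 with an estimated correlation). Mitochondrial ribosomal proteins differed the other way, with interactions above 0 for 41 of 77 and below 0 for 9 (0.415, adjusted p = 0.475 with an estimated correlation). None of the 17 families measured passed camera with an estimated correlation in any contrast, the closest being deubiquitinases named Usp in T-N1G cells at 1.0 µM (adjusted p = 0.0602, 30 of 51 higher and 11 lower).

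As a median over each chromosome, genes of chromosomes 4 and 11 sat lower in T-N1G than in mock cells whatever the treatment. The median log2 difference over 1109 genes of chromosome 11 was -0.22, -0.25 and -0.22 under vehicle, 0.3 µM and 1.0 µM, and over 835 genes of chromosome 4 it was -0.19, -0.17 and -0.23. These comparisons share no library. A hypothesis is that at least part of the T-N1G cells may carry fewer copies of both chromosomes. Of 38 windows of 50 neighbouring genes there, 89.5% lay below 0 in all 3 treatments, against 14.9% of 215 windows elsewhere. The 2 chromosomes stood out by their medians in these same comparisons, so this contrast is partly built in and is no separate evidence. Chromosome 6 also had medians below 0 in all 3 treatments, though smaller ones (-0.066, -0.07 and -0.056). A window of chromosome 4, with gene starts from 62220881 to 94231830, lay above 0 in all 3 (0.335, 0.113 and 0.454). The share required for a shift along whole chromosomes was 90%, so the test stays open by that bound. A copy number change of this size would not reach 2-fold, and without these chromosomes 1597 genes remained called under vehicle.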
